A study of Homo sapiens with 18 samples.

How the data were processed

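Omni-ATAC-seq libraries were made from Raji cells of high or low GFP level at 24, 48 and 72 h, with 3 replicates of each per the labels. The deposited file gives whole-number read counts per peak, not normalised, for 18 columns and 1 shared set of 71318 peaks, each 501 bp wide. Per the submitters' processing notes, FastQC, BWA, deepTools and R 4.2.1 were used with hg38. The role of each tool, the aligner settings, the peak caller, the treatment of duplicate reads and any shift of reads for the transposase cut are not given in the sources used here. These choices could change the counts: duplicates kept would raise the noise of each count, and counting both ends of a fragment would do the same.

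Column headers carry a GFP level, a D number and a V number. D1, D2 and D3 were read as 24, 48 and 72 h, and V numbers were not matched to replicate numbers. Before columns were treated as replicates they were compared. The difference between columns of the same GFP level and time, squared and divided by its counting variance, averaged 1.78 to 1.81 per peak in all 18 such pairs. It was flat over abundance, at a median of 1.80 in the lowest eighth of peaks and 1.81 in the highest. Between times at the same GFP level it was 2.21 to 3.47, and between GFP levels at the same time 4.53 to 7.22. The rise from the lowest to the highest eighth of peaks corresponds to a spread of 0.502%, 4.57% and 8.72% (coefficient of variation) in the same order. In the lowest eighth the median was already 2.34 between times and 3.41 between GFP levels. The spreads given for these kinds of pair are therefore too small, above all for weak peaks. The 3 columns of a group were therefore summed to 1 library. Nothing in the labels says that libraries came from separate cultures. With 1 library per GFP level and time, p-values of the test over times set the GFP contrast against how it varied between the times. That spread may be technical.

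Tests chosen before the data were examined assumed 3 independent libraries per GFP level and time. They were changed once the columns had been compared: the comparison over times used 6 libraries, and comparisons at 1 time, between times and of the interaction were given as counts of peaks with at least a 2-fold difference, with no test. The planned fit on 18 columns is an alternative and concerns differences between libraries. The test over times used edgeR 4.0.16 in R 4.3.3 (TMM scaling, robust quasi-likelihood fit, model of time plus GFP level, 2 residual degrees of freedom) with Benjamini-Hochberg adjustment at 0.05. The biological coefficient of variation was 9.48%. The spread borrowed from other peaks carried a median of 22.6 prior degrees of freedom, so the p-values rest largely on it. The low-count filter of edgeR removed 0 peaks. Log2 CPM (counts scaled to library size) used a prior count of 2. Counting intervals are 95% intervals with the counting variance multiplied by 1.797, and they cover counting error only. Totals were 22908652 to 29790483 counts per library. In data simulated for the comparison over times with 71318 peaks, 69 of 100 peaks changed 1.5-fold and 98 of 100 changed 2-fold were recovered, and 8 unchanged peaks were called. The simulated peaks shared 1 spread and had no effect of time, no trend with abundance and as many rises as falls. The simulation therefore gives no error rate for the real calls, where far more peaks changed.

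Peaks were assigned to 19879 protein-coding genes of a RefSeq table on GRCh38, the assembly of hg38, after 95 readthrough genes were left out. A peak took the gene that contains its centre, or else the nearest within 50 kb, which gave 59536 peaks a gene. The table gives no strand, so promoters were replaced by gene ends, within 1 kb of either end. Exons, introns and UTRs were not separated. Gene lists were tested with camera of limma 3.58.1 at its preset correlation, on the peaks of their genes. Alternatives included DESeq2 1.42.0, other scalings, filters, columns left out and blocks by V number. Motif tests and corrections for GC content need a genome sequence and were not run.

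Named peaks followed a rule fixed before the data were examined. It took the 8 largest rises and falls over times past the threshold with a mean count of at least 30 and the same sign at each time, 1 peak per gene. It also took the 4 largest of each direction at each time without overlap of columns, the 4 with the smallest interaction p and the 3 largest of each direction for time within a GFP level. The peaks at the ends of SMARCA4 and SMARCA2 and those of up to 3 members of each list with the smallest p completed it, and the text names some of these; 1 of the 8 falls is not reported here. For single times and time changes, the thresholds of the rule were those of the 18-column fit.

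Tests of explanations for the height of gene-end peaks were first run on abundance bins 7 to 9 and then on bins 6 to 10. Both forms were dropped, since those bins had been picked after their gaps were seen, and the form reported uses all 10 bins with equal weight. With all bins the test of base composition no longer argued against that explanation. The rule for both base-composition tests was also changed after their values had been seen, from the sign of a median at 48 h to 95% bootstrap intervals at all 3 times. The sign at 48 h alone was dropped, since the direction in which such a trend moves chromosome X was not known.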

Results

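Chromatin accessibility was measured by Omni-ATAC-seq, in which a transposase cuts and tags open DNA, in Raji cells, a B-cell line from a Burkitt lymphoma. Cells were separated by GFP level, high or low, at 24, 48 and 72 h in a series on degradation of SMARCA4 (BRG1), an ATPase of the BAF chromatin remodelling complex, through an auxin-inducible degron. The labels do not say what GFP reports or which level goes with loss of the protein, so the groups are described here only by GFP level. The deposited table held counts in 71318 peaks of 501 bp on hg38 for 18 columns, 3 per GFP level and time, with 7106939 to 11171849 counts each. The 3 columns of a group differed from each other only by a constant multiple of counting noise, and they were counted as 1 library each. The 6 libraries so formed held 22908652 to 29790483 counts, 1 for each GFP level and time, and 3 for each GFP level over the times.

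The main separation among the 6 libraries followed GFP level. The first principal component took 61.7% of the variance and parted the GFP high libraries, at scores of -71.8, -52.9 and -50.4, from the GFP low libraries, at 67.4, 51.7 and 56.0. The second component took 17% and, with D numbers read as time, ordered the libraries by time within both GFP levels, from 31.0 at 24 h to -30.3 at 72 h in GFP high and from 42.2 to -45.3 in GFP low. The 1000 peaks with the most counts took 9.43 to 9.77% of the counts in the GFP high libraries and 10.7 to 11% in the GFP low libraries.

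**Figure D1:**
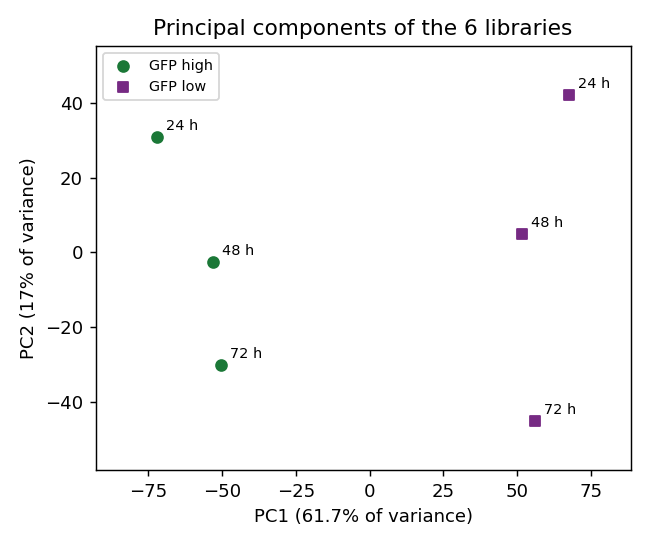
Scores of the 6 libraries on the first and second principal components of log2 CPM, with the share of variance on each axis, green circles for GFP high and purple squares for GFP low. GFP high libraries lie below -50 on the first component and GFP low libraries above 50.

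The first comparison asked which regions differed between GFP low and GFP high cells over the 3 times. The largest falls with a mean count of at least 30 lay away from gene ends. A peak inside PIK3CG fell from 12.6 ± 1.65 CPM (counts scaled to library size) in GFP high to 3.37 ± 0.514 in GFP low. The gene codes for a catalytic subunit of phosphoinositide 3-kinase. These are means and SDs over the 3 times, with 1 library each (n = 3), so the SD includes change with time. The log2 change was -1.89 ± 0.15 (SE, edgeR adjusted p = 2.09e-08). A peak inside EPHB1, an ephrin receptor gene, changed by -1.89 ± 0.15 (adjusted p = 2.09e-08). Among the 8 largest rises with a mean count of at least 30, the peak at a gene end was that of RGS1, a regulator of G-protein signalling. That peak went from 11.7 ± 2.06 to 21.9 ± 2.06 CPM (SD over the 3 times, n = 3). The log2 change was 0.91 ± 0.12 (edgeR adjusted p = 6.09e-06).

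Over all 71318 peaks, edgeR's quasi-likelihood test with a term for time called 18125 peaks lower and 9570 peaks higher in GFP low at a Benjamini-Hochberg adjusted p under 0.05. The lower peaks lay in or near 6107 genes, with a median log2 change of -0.67, and 2855 of them changed at least 2-fold (1656 with loess scaling). The higher peaks lay in or near 6366 genes, with a median of 0.32, and 5 of them changed at least 2-fold. That 5 came to 32 with loess scaling and to 0 with a mean count of at least 30. Of the called peaks, 17904 lower and 9196 higher ones had the same sign at all 3 times. The GFP levels did not overlap in 17917 peaks that were lower and 14836 that were higher, together 45.9% of peaks where chance gives 10%. DESeq2 called 3721 peaks higher, and without the 72 h pair of libraries 2503 were called higher, 2295 of them among the 9570. Loess scaling called 5039 of the 9570 and gave 30 called peaks the opposite sign, and the planned fit on 18 columns called 20711 higher and 21652 lower. The count of higher peaks thus varied with tool, scaling, columns and times.

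The PIK3CG peak is at chromosome 7, 106883514 to 106884014, inside the gene and 18.5 kb from its nearer end, and the EPHB1 peak at chromosome 3, 135066948 to 135067448, 193.3 kb from an end. A peak 43.6 kb outside DHCR7, which codes for the last enzyme of cholesterol synthesis, at chromosome 11, 71383395 to 71383895, changed by -2.11 ± 0.20 (SE, adjusted p = 8.3e-08). Of the 8 largest falls with a mean count of at least 30, 4 had no protein-coding gene within 50 kb. They started at 142041670 on chromosome 8 (-2.13), 72190161 on chromosome 17 (-2.13), 108247520 on chromosome 4 (-1.97) and 54398080 on chromosome 5 (-1.87). Among the 8 largest rises with that mean count, the RGS1 peak at chromosome 1, 192580368 to 192580868, lies 0.6 kb outside the gene. Peaks inside SEL1L3 (0.88 ± 0.16), TUSC3 (0.87 ± 0.19) and NSUN7 (0.86 ± 0.18) and 27.5 kb outside the collagen gene COL4A1 (0.94 ± 0.20) also rose. The remaining 3 rises had no gene within 50 kb and started at 63935623 on chromosome 10, 64922494 on chromosome 2 and 14799800 on chromosome 6, at log2 changes of 0.90, 0.89 and 0.86.

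**Figure D2:**
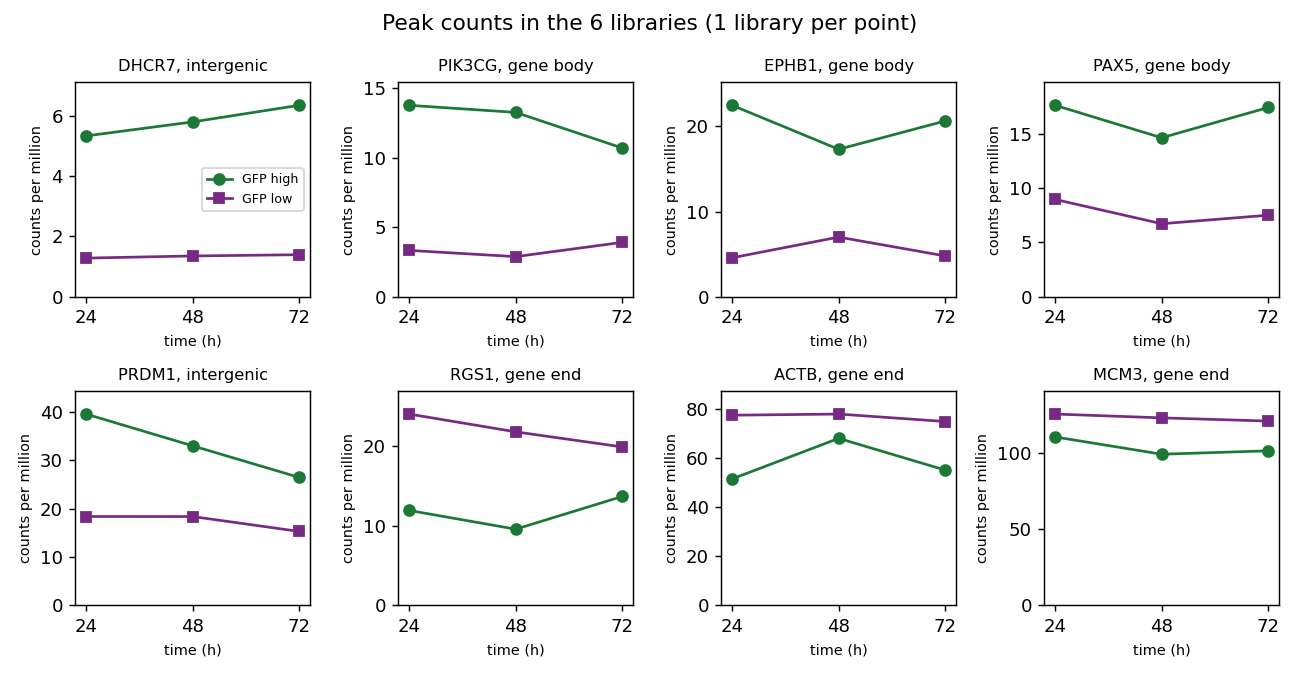
CPM, counts scaled to library size (vertical axis) against time in hours for peaks of 8 genes, with green circles for GFP high and purple squares for GFP low, 1 library per point. DHCR7, PIK3CG, EPHB1, PAX5 and PRDM1 are lower in GFP low at each time, and RGS1, ACTB and MCM3 are higher, although the MCM3 change came to -0.01 with loess scaling. The DHCR7 and PRDM1 peaks lie 43.6 and 32 kb outside the genes.

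At SMARCA4 itself, the gene-end peak (chromosome 19, 10960534 to 10961034) held 15.4 ± 3.74 CPM in GFP high and 18.1 ± 2.44 in GFP low (SD over the 3 times, n = 3). The difference did not pass the edgeR test (0.24 ± 0.14, adjusted p = 0.15). Of the peaks at the ends of SMARCA2, which codes for the alternative BAF ATPase, the peak at chromosome 9, 2014916 to 2015416, rose by 0.20 ± 0.06 (adjusted p = 0.00878), a call lost with DESeq2, without the 48 or 72 h pair and with loess scaling, where it came to -0.04. The other, at 2015853 to 2016353, did not pass (0.09 ± 0.10, adjusted p = 0.514). Degradation acts on the protein, so accessibility at the gene does not check the labels. Among the 24 genes of BAF subunits, 23 had a peak, 7 had only higher peaks, 3 only lower, 2 both and 11 neither. A peak 46.6 kb outside ARID1B changed by -1.27 ± 0.16 (adjusted p = 2.82e-06) and a gene-end peak of ARID2 by 0.28 ± 0.07 (adjusted p = 0.00384), which came to 0.08 and lost its call with loess scaling.

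Position relative to genes separated the directions. Of 13716 peaks within 1 kb of an end of a protein-coding gene, 34.4% were called higher and 4.24% lower. Of 30807 peaks in gene bodies, 7.98% were higher and 30.3% lower, and of 26795 intergenic peaks, 8.96% were higher and 30.6% lower. Gene ends made up 3.21% of the lower peaks against 24.7% of the rest (odds ratio 0.101, 95% interval 0.0926 to 0.110, Fisher's exact test, two-sided). They made up 49.2% of the higher peaks against 14.6% of the rest (odds ratio 5.68, 95% interval 5.43 to 5.95). Gene-end peaks were also the more abundant, at a median of 23.6 CPM against 6.76 in gene bodies and 6.15 between genes, and in 10 bins of abundance their excess of higher calls lay in the top bins. In bin 10, 70.6% of gene-end, 34.9% of gene-body and 27.6% of intergenic peaks were higher, but in bin 5 these shares were 4.28%, 7.53% and 9.91%, and gene ends had the lowest share in each of bins 1 to 7. Lower calls were rarer at gene ends in every bin, at 13.2% against 32.7% and 29.8% in bin 5 and 0.349% against 13.8% and 21.6% in bin 10. The enrichment among higher peaks turned with loess scaling, to an odds ratio of 0.672, while that among lower peaks did not (0.125). Neighbouring peaks are not independent, and the intervals cover counting only.

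**Figure D3:**
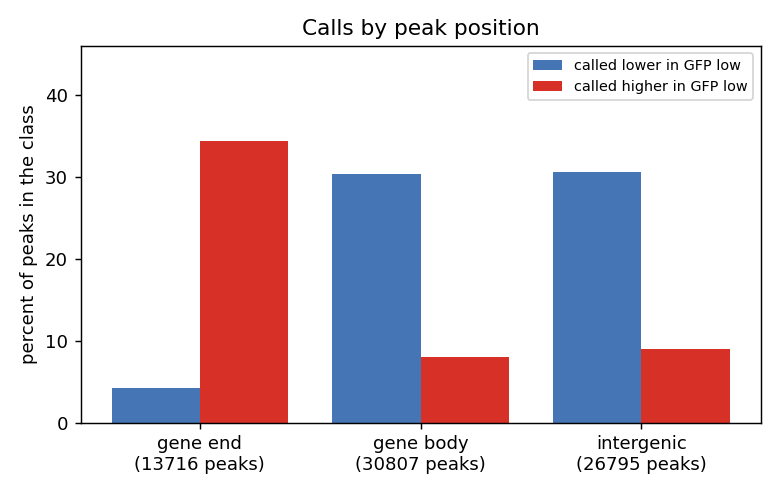
Percent of the peaks in each position class (vertical axis) called lower, in blue, or higher, in red, in GFP low. Gene ends hold 34.4% higher and 4.24% lower peaks, while gene bodies and intergenic peaks hold 30.3% and 30.6% lower.

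Of the peaks of B-cell identity regulators, 28.9% were lower, against 25.4% of all peaks, and the list did not pass against other peaks (camera, adjusted p = 0.195). Only 9.51% of its peaks lay at gene ends, where lower calls were rare, against 19.2% of all peaks. That position alone raises the share of lower peaks to be looked for in the list. All 20 genes of that list had a peak, and 13 had only lower called peaks, 6 had both and 1 had neither. Peaks inside PAX5, the B-lineage commitment factor (-1.10 ± 0.12), 5.2 kb outside IKZF1, which codes for Ikaros (-0.93 ± 0.10), and 48.5 kb outside MEF2C (-1.17 ± 0.16) fell (adjusted p = 3.37e-07, 4e-07 and 4.77e-06). Of its 305 peaks, 85 were lower and 14 higher adjusted over the list alone, against 88 and 17 over all peaks.

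Of the 17 lists fixed before the data were examined, camera placed memory B-cell genes (adjusted p = 0.0275) and T-cell markers (adjusted p = 0.0302) below other peaks. Neither was called with an estimated correlation (camera, adjusted p = 0.513 for both) or among peaks away from gene ends alone. The setting with an estimated correlation rests on 2 residual degrees of freedom, so it could hardly call any list and does not decide. The correlations themselves were estimated at 0.00124 and 0.00828, below the preset value. With loess scaling and without the 24 h pair, the memory B-cell list kept its call (adjusted p = 0.0178 and 0.0241) and the T-cell list did not (0.0519 and 0.0522). Among gene-end peaks alone the T-cell list was called (adjusted p = 0.000294) and the memory B-cell list was not (0.084). That test did not match peaks for abundance. The median change of gene-end peaks was -0.098 in abundance bin 2 and 0.223 in bin 10, so a list of weak peaks may be called lower for that reason. In the memory B-cell list, 18 of 18 genes had a peak, 5 had only lower peaks, 1 only higher, 9 both and 3 neither, and 60 of 162 peaks were lower adjusted over the list alone (59 over all peaks). Its examples were peaks outside TLE3, a transcriptional corepressor (-1.39 ± 0.17), FCRL5, an Fc receptor-like gene (-1.14 ± 0.16), and the integrin gene ITGB1 (-0.90 ± 0.12). Of the T-cell markers, listed as genes of another cell type, 12 of 14 had a peak and 9 had only lower peaks, 1 only higher and 2 neither. Examples were peaks outside the T-cell surface genes CD28 (16.8 kb, -0.92 ± 0.10) and CD2 (25.7 kb, -1.49 ± 0.21) and the kinase gene LCK (1.1 kb, -0.60 ± 0.11).

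The remaining B-cell lists did not pass against other peaks. Among gene-end peaks alone, again not matched for abundance, plasma cell genes (adjusted p = 1.61e-05) and B-cell receptor signalling (adjusted p = 0.0136) were called lower. With an estimated correlation, over all peaks, these lists had adjusted p = 0.513 and 0.8. For germinal centre dark zone genes (adjusted p = 0.443), 47 of 156 peaks fell and 20 rose. Falls lay outside MYBL1 (16.8 kb, -1.42 ± 0.12), BCL6 (32 kb, -0.96 ± 0.12) and EZH2 (19.4 kb, -1.07 ± 0.14). For light zone and CD40 genes (adjusted p = 0.938), 33 of 139 fell and 20 rose. Falls lay inside CD86 (-0.81 ± 0.12), 18.2 kb outside CCL22 (-0.87 ± 0.13) and 40.6 kb outside MYC (-0.87 ± 0.14). For plasma cell genes (adjusted p = 0.195), 26 of 70 fell and 5 rose. Falls lay 32 kb outside PRDM1, which codes for the plasma cell factor BLIMP1 (-0.92 ± 0.11), and inside CD38 (-0.92 ± 0.12) and ELL2 (-1.13 ± 0.22). For B-cell receptor signalling (adjusted p = 0.0952), 70 of 221 fell and 14 rose, including DAPP1 (-1.59 ± 0.16), PIK3AP1 (-1.16 ± 0.14) and the kinase gene LYN (-0.45 ± 0.06). For migration genes (adjusted p = 0.523), 29 of 97 fell and 10 rose, with a peak 46 kb outside ITGA4 at -0.78 ± 0.11.

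Lists of other functions also held peaks of both directions. Cell-cycle genes (adjusted p = 0.0952, 0.8 with an estimated correlation, and 0.0402 as higher in the fit on 18 columns with a replicate block within time) had 56% of their peaks at gene ends, where 13716 of all 71318 peaks lay. They had 15 of 50 peaks higher and 4 lower. The higher ones included gene-end peaks of MCM3 (0.25 ± 0.05) and CCNE2 (0.27 ± 0.06) and a peak 20.8 kb outside CCNE1 (0.41 ± 0.09). With loess scaling MCM3 came to -0.01, and CCNE2, TBP and CD74 lost their calls at 0.07, 0.08 and 0.02. Housekeeping genes (adjusted p = 0.248) had 14 of 60 higher and 8 lower, with gene-end peaks of ACTB at 0.41 ± 0.07 and TBP at 0.31 ± 0.06, and a peak 9.5 kb outside PPIA at -0.80 ± 0.11. Interferon response genes (adjusted p = 0.728) had 14 of 58 peaks lower and 9 higher. Falls lay at a gene end of ISG20 (-0.84 ± 0.12), 16.9 kb outside IRF1 (-0.78 ± 0.12) and inside IFIT3 (-0.58 ± 0.09). For AP-1 and MAF genes (adjusted p = 0.728) 15 of 90 fell and 14 rose, with a peak 19.1 kb outside BATF3 at -0.91 ± 0.16. For p53 response and apoptosis genes (adjusted p = 0.879) 29 of 124 fell and 18 rose, with a peak 15 kb outside PMAIP1 at -0.97 ± 0.13. BAF subunits (adjusted p = 0.728) had 29 of 155 peaks lower and 18 higher. Only 5 of 15 genes of MHC class II presentation had a peak (adjusted p = 0.511), and the others were not analysed here. Gene-end peaks of RFXANK and CD74 stood at 0.44 ± 0.11 and 0.23 ± 0.06, and a peak 13 kb outside RFXAP at -1.37 ± 0.20. Among gene-end peaks alone, again not matched for abundance, interferon genes (adjusted p = 0.0249), myeloid markers (0.0248) and epithelial and stromal markers (0.00296) were called lower. With an estimated correlation, over all peaks, these lists had adjusted p = 0.889, 0.513 and 0.889. The interferon list showed no clear direction over all peaks, with a median of 0.063 and a mean of -0.038. Over all peaks, myeloid markers (adjusted p = 0.0987) had 9 of 20 peaks lower and 1 higher, among them a gene-end peak of ITGAM (-0.80 ± 0.15). Epithelial and stromal markers (adjusted p = 0.728) had 7 of 28 lower and 3 higher, among them a peak 32.5 kb outside EPCAM (-1.05 ± 0.15).

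The second set of comparisons asked how GFP low differed from GFP high at each time. At 24 h, the intergenic peaks at 54398080 on chromosome 5 and 37549007 on chromosome 10 were among the lowest, at log2 differences of -2.65 (95% counting interval -3.28 to -2.02) and -2.69 (-3.40 to -1.98). At 48 h, peaks inside CD163L1 (-2.44, -3.22 to -1.66), CHCHD3 (-2.26, -2.98 to -1.54) and DLEU7 (-2.21, -3.0 to -1.42) led. At 72 h, the DHCR7 (-2.13, -2.79 to -1.47) and EPHB1 (-2.09, -2.45 to -1.73) peaks and a peak 34.5 kb outside WDR1 (-2.07, -2.45 to -1.70) were among the lowest. Among the highest at 24 h were CDC14A at 1.42 (0.88 to 1.96) and FANCC at 1.30 (0.68 to 1.93). OXCT1 led at 48 h, at 1.54 (0.96 to 2.12), with KCNJ6 at 1.40 (0.82 to 1.97). At 72 h a peak 11.4 kb outside EIF2AK3 led, at 1.22 (0.60 to 1.83), with PRKAA1 at 1.18 (0.54 to 1.81).

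Each time had 1 library per GFP level, so these differences had no replicate check, and an interval compares those libraries, not the conditions. In GFP low 5822 peaks were at least 2-fold lower at 24 h, 2746 at 48 h and 2732 at 72 h, and 151, 161 and 65 were at least 2-fold higher. With V numbers read as time the falls were 3322, 3450 and 3272, so the larger number at 24 h holds for D numbers read as time. The counts of higher peaks were less steady, at 659, 326 and 249 with loess scaling, 74, 71 and 32 with a mean count of at least 30, and up to 350, 345 and 170 with 1 column left out. The falls at 72 h came to 1749 with loess scaling. Across peaks, which are not independent replicates, the log2 changes at 24 and 48 h correlated with Pearson's r = 0.675, those at 24 and 72 h with 0.725 and those at 48 and 72 h with 0.713. The median change of gene-end peaks was 0.26 at 24 h, 0.08 at 48 h and 0.17 at 72 h, and that of gene-body peaks was -0.10, -0.09 and -0.09.

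**Figure D4:**
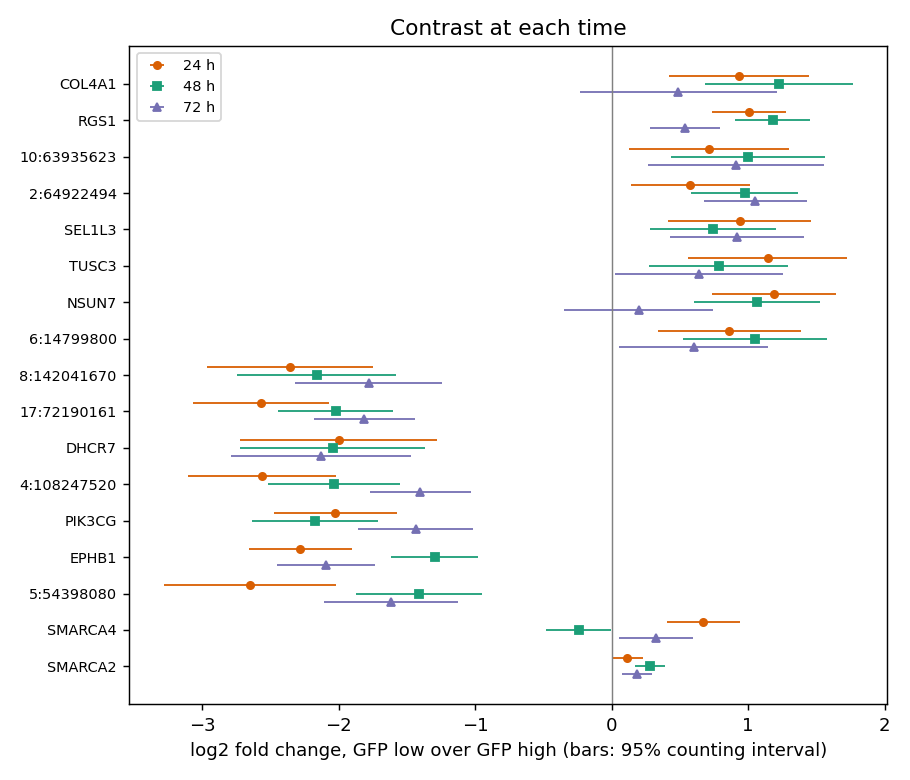
Log2 fold change of GFP low over GFP high (horizontal axis) at 24 h (circles), 48 h (squares) and 72 h (triangles) for peaks with the largest changes averaged over times and for SMARCA4 and SMARCA2. Bars are 95% counting intervals from 1 library per group, and the SMARCA4 values lie on both sides of 0.

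Change with time was examined within each GFP level and as a difference between them. In GFP low, a peak inside MYO9A differed by 2.08 on the log2 scale between 24 and 72 h and a peak inside ADARB2 by -2.41. In GFP high the same MYO9A peak differed by 1.63, and peaks of ATP8B4 and ADGRB3 by -1.86 and -1.76. A peak inside FMN2 stood at -0.94 (-1.10 to -0.78) for GFP low over high at 24 h and at -0.06 (-0.18 to 0.07) at 72 h. From 24 to 72 h, 60 peaks were at least 2-fold higher and 427 at least 2-fold lower in GFP high, and 451 and 779 in GFP low. These counts hold for D numbers read as time: with V numbers read as time they were 13 and 6 in GFP high and 20 and 12 in GFP low. The 60 came to 123 with loess scaling, 36 with a mean count of at least 30 and 72 to 163 with 1 column left out, and with that mean count the 427 came to 255 and the 451 to 300. The contrast between GFP levels was at least 2-fold further up at 72 h in 774 peaks and further down in 424, against 163 and 161 under the other reading and 442 and 231 with a mean count of at least 30. In the peaks called lower over the times, the median change from 24 to 72 h was -0.11 in GFP high and 0.06 in GFP low, and in the peaks called higher it was 0.04 and -0.03. With 1 library per group none of these time differences could be tested against replicates.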

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

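The comparison of opposite signs between times was set after the data had been seen. In 4 named peaks the contrast between GFP low and high went opposite ways at a pair of times, beyond the counting intervals. It did so in every column, but the columns of a group count as 1 library, so this adds no replicate check. The difference between the times was not tested. At the gene end of SMARCA4 the log2 contrast was 0.67 at 24 h and -0.24 at 48 h, 0.92 apart. A peak inside ADARB2, a gene of the RNA-editing deaminase family, stood at 0.99 at 24 h and -1.18 at 72 h, 2.16 apart. A peak inside MYRFL stood at 0.33 at 72 h and -0.53 at 24 h, 0.86 apart. An intergenic peak at 121724403 on chromosome 8 stood at 0.34 at 48 h and -0.46 at 24 h, 0.80 apart. The MYRFL and chromosome 8 peaks had been named for a small interaction p, and the ADARB2 peak for its time change in GFP low. Opposite signs were thus favoured by how these were picked, and only named peaks were searched. Away from gene ends, the median contrast of all chromosome 19 peaks was 0.12 at 24 h and -0.11 at 48 h.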

How the results depend on the processing

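Tests without a time term, without a time pair, without chromosome X, with V numbers read as time, with the nearest gene end or away from gene ends were chosen after seeing the data. Lower peaks averaged over times stayed within 1.5 times of 18125 in all settings but a fold threshold of 1.5, which left 2764 lower and 3 higher peaks, since it asks for more than a difference from 0. For the other changes below the cause was not tested, apart from stricter filters, which leave fewer peaks. Peaks called higher numbered 3721 with DESeq2 and 20711 in the fit on 18 columns planned beforehand, which became an alternative once columns had been compared, and without a time pair or a column 2503 to 9609, lowest without 72 h. Column totals rose with the V number in each group, as from 7106939 to 8587396 counts in GFP high at 24 h. Deviations of peaks from the group mean did not pair the columns by V number (correlations -0.0028 to 0.0132 in 9 pairs). The replicate block by V number called 20747 peaks higher, and within time 20668. Of lower peaks changed at least 2-fold, loess scaling left 1656. Of the 5 higher ones, loess gave 32, a mean count of at least 30 gave 0, the fold threshold 1, and leaving out a pair or column 3 to 20. At 24, 48 and 72 h loess gave 659, 326 and 249 at least 2-fold higher peaks, the mean count filter 74, 71 and 32, and left-out columns 187 to 350, 194 to 345 and 86 to 170. Loess also left 1749 lower peaks at 72 h. With V numbers read as time, 24 h gave 3322 lower and 99 higher peaks, and 48 h gave 84 higher. For the difference of contrasts the filter gave 231 down and 442 up, and the V reading 161 and 163. For time in GFP high the filter gave 255 down and 36 up, the V reading 6 and 13, loess 123 up, and left-out columns 72 to 163 up. For time in GFP low the filter gave 300 up, and the V reading 12 down and 20 up. The odds ratio of gene ends among higher peaks turned to 0.672 with loess. Lists called lower went from 2 to 0 with an estimated correlation, which at 2 residual degrees of freedom could hardly call any list. They came to 0 away from gene ends, 1 with loess and 1 without 24 h. On gene-end peaks, not matched for abundance, 6 were called: plasma cell, T-cell, epithelial and stromal, B-cell receptor signalling, myeloid and interferon genes. The interferon list, called there at adjusted p = 0.0249 (camera), had no call over all peaks. The replicate block within time called 1 list higher, the cell-cycle genes (adjusted p = 0.0402). With loess scaling MCM3 came to -0.011 and SMARCA2 to -0.035, and MYRFL ranged from -0.26 to 0.18 with pairs or columns left out. Scaling moved the median of all peaks from 0.03 to between 0.01 and 0.05. Filtering of low counts removed 0 peaks, so no filter and the filter are the same test, and fits with GC offsets and motif tests were not run.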

Other observations

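Falls gathered at some gene loci. Among 1431 genes with at least 8 peaks away from gene ends, 25 held more lower peaks than the 29.4% of the background (hypergeometric test, adjusted p under 0.05). By the same test, 0 held more higher peaks than their background of 8.57%. At an unadjusted p under 0.05 there were 50 such genes of the 1431, a share below 0.05 and so no excess over chance. NCKAP5 led, with 18 of 22 peaks lower (adjusted p = 0.000761), followed by the thyroglobulin gene TG with 12 of 14 (adjusted p = 0.0101) and the receptor phosphatase gene PTPRG with 22 of 34 (adjusted p = 0.0101). HIVEP3, which codes for a zinc-finger factor, had 19 of 28 lower (adjusted p = 0.0104), and RGCC had 8 of 8 and SETBP1 11 of 13 (adjusted p = 0.0118 for both). The NOTCH coactivator gene MAML2 (17 of 25), the tetraspanin gene CD9 (9 of 11) and TLE3 (9 of 11) also passed. ZBTB38 came first for higher peaks, with 6 of 12, and did not pass (adjusted p = 0.332). These loci were sought after the data had been seen, and neighbouring peaks are not independent.

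All tests of explanations in this part were chosen after the results had been seen. Falls of at least 2-fold outnumbered rises of that size. Such falls outnumbered rises by 5822 to 151 at 24 h, 2746 to 161 at 48 h and 2732 to 65 at 72 h. The GFP low library was the deeper of its pair at 24 h (27646157 against 22908652 counts) and 72 h (29790483 against 24677828). At 48 h it was slightly the shallower (28161886 against 29503529). An excess of falls set by which library was deeper would have turned at 48 h, and it did not. This argues against a difference in depth as the whole cause, although the gap at 48 h was small. Over the times, medians of position class and abundance bin ran from -0.133 to 0.223 in log2. A shift shared by a whole bin was thus too small to make 2-fold falls by itself. With these medians taken out, 2205 peaks lay at least 2-fold below and 14 above. Medians so small could hardly have evened the counts, so the centring does not decide. A trend of efficiency with peak abundance that spreads peaks unevenly within a bin stays open. The 10 splits of the 6 libraries are too few for a share under 0.05: 1 split, the real one, called 27695 peaks and the highest other called 0. Every other split also mixed the GFP levels on each side, which puts the GFP difference into its spread. Few calls were therefore likely in those splits, and they do not decide. GC content was not tested, and the GFP level itself, whose link to SMARCA4 the labels do not state, stays open as an explanation that may account for the falls.

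Gene-end peaks lay above other peaks of like abundance on average, but not at every abundance: in 10 bins the gap of medians was 0.08 to 0.23 in log2 in bins 6 to 10, and -0.03 to 0.05 with intervals that reached 0 in bins 1 to 5. Averaged over the times, a trend with abundance alone is argued against in these libraries by the mean gap over all 10 bins. It was 0.082 with a lower 95% bootstrap bound of 0.071. The bootstrap drew single peaks, so this bound holds no variation between libraries. The mean gap differed far more between the times, and its interval reached 0 at 48 h. The height of gene-end peaks above 0 depended on scaling, since their median was 0.18 with TMM and 0.09 with loess scaling. A trend with base composition stays open and may account for the gap: at 48 h, where chromosome 19 lay below chromosome 4 by 0.10, the mean gap was 0.012 (-0.003 to 0.028), against 0.178 at 24 h, where chromosome 19 lay above by 0.27. At 72 h the mean gap was 0.089 (0.071 to 0.103) with chromosome 19 minus chromosome 4 at -0.02 (-0.053 to 0.016), so the gap followed that difference in order over the times, and GC content itself was not tested.

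Peaks of chromosome X lay above those of autosomes, by 0.15 in log2 away from gene ends, and by 0.15, 0.14 and 0.11 at 24, 48 and 72 h. An extra copy of the whole chromosome in GFP low cells would raise all classes alike if it were as open as the rest. Gene-end peaks were raised by 0.029 (95% bootstrap interval 0.019 to 0.041) and other peaks by 0.153 (0.124 to 0.180). This bears only on such a copy, and a less open one was not tested. Peaks were not matched for abundance, and the bootstrap drew peaks, so its intervals hold no variation between libraries. In windows along the chromosome, away from gene ends, 15 of 16 medians lay above autosomes, and the first lay below (-0.12). The trend that moves chromosome 19 against chromosome 4 had opposite signs at 24 and 48 h, so a shift of chromosome X that it caused would have turned between them, but the shift was 0.148 (0.107 to 0.178) and 0.143 (0.115 to 0.165). A base-composition effect of the same sign at all times stays open, since GC content was not tested and chromosome 22 had the lowest median away from gene ends at 48 h (-0.288) and 72 h (-0.233), though not at 24 h (-0.105). Apart from an extra copy as open as the rest, no biological explanation was tested, and a shift tied to GFP level may remain.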
